A study of Caenorhabditis elegans with 2 samples.

How the data were processed

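Chromatin immunoprecipitation followed by sequencing was carried out on early embryos of the nematode Caenorhabditis elegans, collected 0 h after the culture had been synchronised by bleaching (bleach kills worms and spares eggs). The strain OP642 carries a transgene in which the protein encoded by B0310.2 ends in GFP and FLAG tags, in an unc-119 mutant background, and an antibody to GFP was used for the precipitation, per the labels. Chromatin was sheared by sonication. There were 2 samples, labelled as biological replicates 1 and 2 of a single group, so no comparison between conditions was possible and the comparisons are between replicates and between the peaks and the rest of the genome.

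The starting material was the deposited region lists. Per the deposited descriptions of the files, a list of peaks and background regions was made from each replicate's alignment together with a control alignment, and a further list from the alignments of both replicates pooled. Each of these lists held 30000 regions. The optimal list holds the regions that passed a threshold on the irreproducible discovery rate (IDR), a measure of how consistently regions rank in replicates. Each list was deposited for builds ce11 and ce10. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here, and neither is the treatment of reads that align to several places. Per the deposited format descriptions, the authors' lists give for each region a signal value, and this signal is the measure used here to rank regions within a list. Its scale was not stated, so signal was never compared between lists as a level. The authors' lists also give a −log10 q value for each region, which was between 1.99 and 2.47 for the optimal ce11 peaks and was used only to describe them. The signal and the position of every peak are the authors' own. The lists hold no read counts, so the depth of each sample is unknown and no interval that needs it is given.

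All chromosome names and coordinates of the ce11 lists were within the chromosome lengths of assembly WBcel235, which is the sequence of ce11, and the ce11 lists were therefore annotated with Ensembl release 115 gene models. Isotypes of tRNA genes came from the RefSeq annotation of the same assembly. The ce10 lists were used for counts and for comparisons within that build, and no coordinate was converted between builds. Coordinates are 1-based.

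The optimal ce11 list was the main peak set. A summit was counted at a promoter if it lay from 1000 bp upstream to 300 bp downstream of the 5' end of a protein-coding transcript. Summits outside promoters were assigned, in this order, to 5' UTR, coding exon, intron, 3' UTR, noncoding gene and intergenic sequence. Shares were compared with 1000 random placements of the summits within their own chromosomes, by a two-sided permutation test whose smallest possible p is 0.002. A summit was counted near a tRNA, snRNA, snoRNA, miRNA or rRNA gene if it lay within 200 bp of the gene, and p-values were adjusted over the 5 classes by the Benjamini-Hochberg method. The same test was repeated with random positions drawn inside promoters. Where small RNA genes are named as a set, they are tRNA, tRNA pseudogene, snoRNA and snRNA genes, and miRNA genes are not included. Chromosomes were compared with a two-sided exact binomial test against their share of the length of the 6 nuclear chromosomes and against their share of protein-coding genes, with intervals at 95% by the exact method that cover counting error only.

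Gene lists were tested with two-sided Fisher's exact tests of members with a promoter peak against all other protein-coding genes, adjusted over 18 lists. The lists were ribosomal proteins, translation factors and aminoacyl-tRNA synthetases, proteasome subunits, mitochondrial respiratory chain, mRNA splicing, core histones (by the his- name, which takes in linker histones), cell cycle and mitosis, maternal and germline regulators, endoderm and mesendoderm regulators, other embryonic lineage regulators, homeobox ceh genes, nuclear hormone receptors, stress response, muscle structure, pan-neuronal genes, intestine terminal genes, cuticle collagens and chemoreceptors. Genes that share a promoter peak are not independent, so the number of distinct peaks behind the count is given for each list that passed. Sequences of 6 bases (6-mers, with reverse complements joined) were tested for presence in the window reaching 50 bp to each side of the summit against windows of the same width centred 500 bp to each side, with Fisher's exact test and adjustment over the 2080 6-mers. The flanks are not matched to the summits in base composition, so the test was repeated, as an alternative added after seeing the data, against 2 windows per peak drawn from the same chromosome with the same number of G and C bases. An adjusted p under 0.05 was the threshold throughout.

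Replicates were compared by the share of replicate 1's top 642 regions that overlapped replicate 2's top 642 by at least 1 bp, beside 1000 shuffles within chromosomes. The signal of the strongest overlapping region in each replicate was also compared across peaks, with 100000 permutations, whose smallest possible two-sided p is 2e-05. These values are across peaks, which are not independent replicates.

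The protein-coding genes named from promoter peaks, and the 5 6-mers, were chosen by a rule fixed before the data were examined. The genes were the 20 protein-coding genes reached by going down the peaks by signal and taking, for each peak in a promoter, the gene with the nearest 5' end among those whose promoter held the summit. To these were added the 4 members with the strongest peak of each list that passed the test, up to 2 members of every other list, B0310.2 and unc-119, and the 5 most significant of the 6-mers more frequent at summits. The noncoding genes, frm-7 and the other 6-mers named were chosen after their values were seen. The tests, the lists and the alternatives were also fixed before the data were examined, except where a test, a set or an alternative is said to have been added or chosen later. Alternatives changed the promoter window, the assignment of peaks to genes, the distance to noncoding genes, the windows of the 6-mers, the overlap rule, the build, the set of peaks and the replicates used.

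The steps were tested on simulated data. When 8 proteasome genes were given a summit among 642 simulated summits, 8 were recovered and the list passed the test. When 32 summits were placed at tRNA genes, 33 were counted near tRNA genes. A single planted 6-mer was returned as the most significant of 5 called. With nothing planted, 0 lists and 0 6-mers passed. Those summits were placed at random, so this result does not cover the real summits, which were richer in G and C than their flanks. Analyses used Python 3.11.15, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Signal tracks, alignments and the control library were not used here.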

Results

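Binding of GFP-tagged B0310.2 protein was mapped in early C. elegans embryos by anti-GFP chromatin immunoprecipitation and sequencing in 2 biological replicates. B0310.2 is annotated as a putative zinc finger protein and is encoded on the X chromosome (ce11, X: 501946 to 506948, minus strand). The data were 30000 ranked regions per replicate, the same number for the pooled replicates, and the list of peaks that the authors retained after IDR thresholding. The question addressed is where in the embryonic genome the tagged protein was found, and how far the replicates gave the same map. The depth of the samples is unknown, because the region lists give no read counts.

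The authors' IDR-thresholded list held 642 peaks in ce11 and 617 in ce10. The 642 ce11 peaks were the 642 strongest regions of the pooled list. Their signal ran from 139.6 to 1118 with a median of 186, and 569 of them were 476 bp wide. Every one of the 642 peaks overlapped a region in the list of each replicate. Each list holds 30000 regions, background included, and the pooled list comes from the same alignments, so this overlap says little about agreement. Of these peaks, 570 (88.8%) were among the top 642 regions of replicate 2 and 447 (69.6%) among the top 642 of replicate 1. A stricter set of 398 peaks (62.0%) ranked that high in both.

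The strongest peaks ranked high in both replicates. Of the 10 strongest peaks, 10 were among the 10 strongest regions of replicate 1 and 9 among the 10 strongest of replicate 2. Of replicate 1's top 642 regions, 403 (62.8%) overlapped a top 642 region of replicate 2, against a mean of 0.624% and a highest value of 1.87% when the regions were shuffled (permutation p = 0.002, the smallest the shuffles can give). Across the 642 peaks the replicates' signals were correlated with Spearman's rho = 0.637 and Pearson's r = 0.772 on log2 signal (permutation p = 2e-05 for each, the smallest 100000 permutations can give). The 642 peaks were the strongest regions of the pooled list, which was made from the alignments of both replicates. This correlation and its p therefore describe a set chosen on the same data and are no independent measure of agreement. The strongest region overlapping a peak ranked as low as 16171 in replicate 1 and 1629 in replicate 2. Nearby peaks sometimes took the same region, so that the comparison rested on 616 distinct regions in each replicate. The log2 ratio of the replicates' signals had an SD of 0.43 across peaks. The median distance between the replicates' summits was 33 bp.

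**Figure D1:**
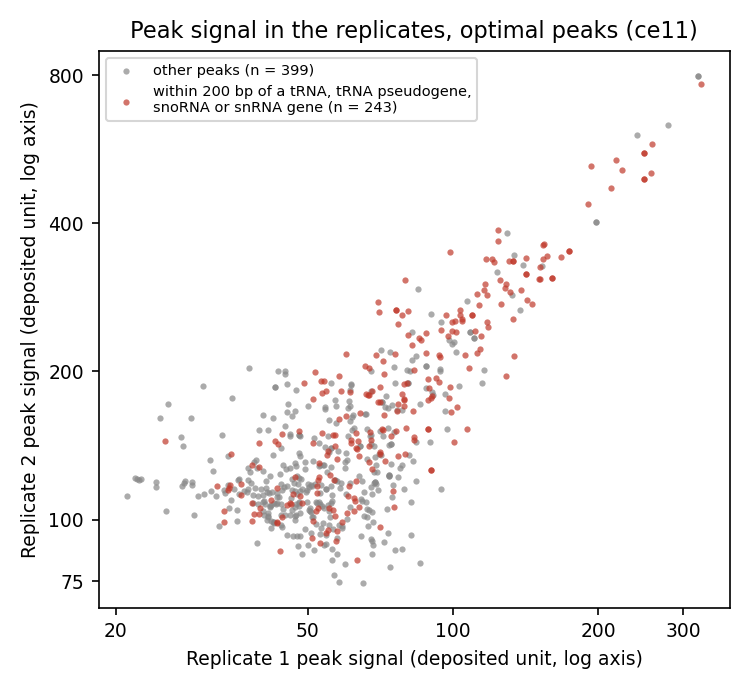
Signal of the strongest region overlapping each of the 642 peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log axes in the deposited unit. Each point is a peak, and red points are the 243 peaks with a tRNA, tRNA pseudogene, snoRNA or snRNA gene within 200 bp, which make up 75 of the 100 strongest peaks.

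Small noncoding RNA genes lay beside many of the strong peaks. Of the 642 summits, 170 (26.5%) lay within 200 bp of a tRNA gene, against a mean of 0.292% and a highest value of 1.09% in random placements, a 90.8-fold difference. A snoRNA gene, whose product guides the modification of ribosomal and other RNAs, lay within 200 bp of 58 summits (9.03% against 0.183%). An snRNA gene, a class that includes spliceosomal and spliced leader RNAs, lay near 15 summits (2.34% against 0.0539%), and a miRNA precursor gene near 12 (1.87% against 0.126%). Each of these 4 classes had an adjusted p of 0.0025 by permutation, which is the value the smallest possible p gives, and the same adjusted p when random positions were drawn inside protein-coding promoters. That second comparison still used all 642 summits, in promoters or not, so it is no test within promoters. No summit (0 of 642) lay near any of the 20 annotated rRNA genes, where random placements had a mean of 0.0157% (permutation p = 1). With a mean that low, this count could not show a depletion.

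Seen from the genes, 175 of the 612 nuclear tRNA genes (28.6%), 57 of 346 snoRNA genes (16.47%), 14 of 129 snRNA genes (10.9%) and 16 of 261 miRNA genes (6.13%) had a peak. The peaks near tRNA, tRNA pseudogene, snoRNA or snRNA genes, called small RNA genes from here on, numbered 243 (37.9%). The term leaves out miRNA genes, and the 12 peaks near a miRNA gene are among the other 399. The 243 peaks made up 54.5% of the stronger 321 peaks and 21.2% of the weaker 321 (Fisher's exact test, two-sided, p = 2.4e-18). This test and the joined set of small RNA genes were chosen after seeing the data. Shares near snoRNA and snRNA genes were 15.3% and 3.74% in the stronger 321 peaks. In the peaks ranked high in both replicates, an alternative added after seeing the data, 3.02% lay near a miRNA gene and 13.8% near a snoRNA gene.

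The summits took different positions at the different classes. At tRNA genes the summit lay a median of 27.5 bp downstream of the 5' end (quartiles 5.25 and 53.8 bp), which is inside the transcribed gene. At snoRNA genes the median position was -44 bp, upstream of the 5' end (quartiles -55 and -18.5 bp). At snRNA genes it was 128 bp downstream (quartiles 39 and 156 bp). These distances describe the classes and were not tested against each other.

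**Figure D2:**
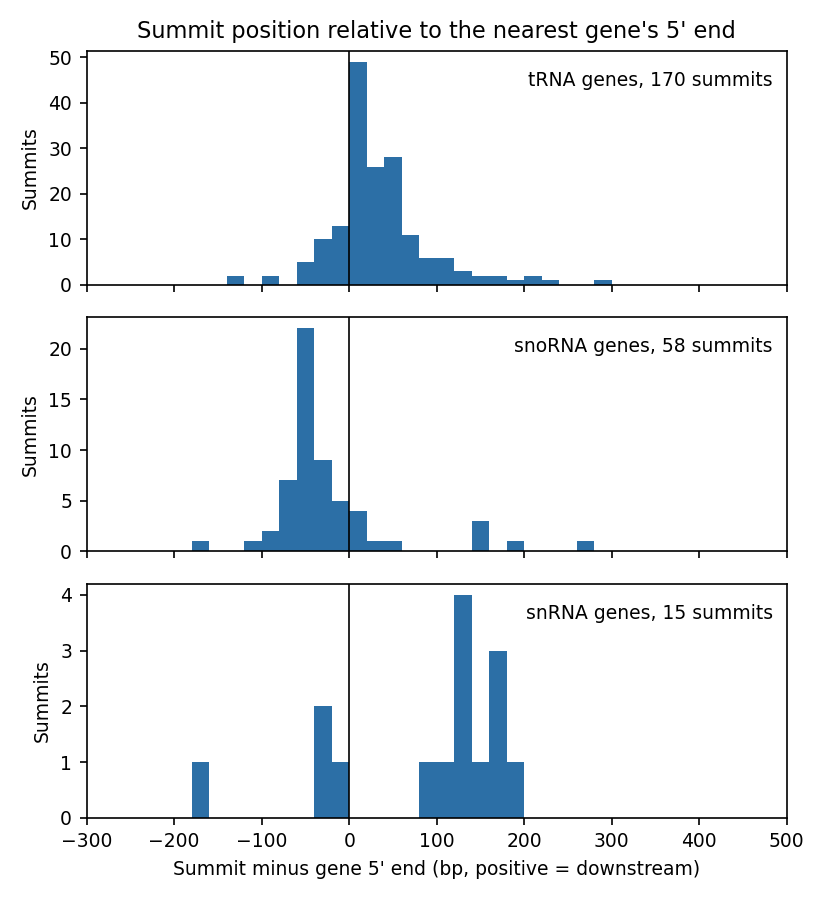
Histograms of the distance from the 5' end of the nearest tRNA, snoRNA or snRNA gene to the summit, in bp, for the 170, 58 and 15 summits within 200 bp of such a gene (y axis, number of summits; positive is downstream). Medians were 27.5 bp, -44 bp and 128 bp.

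Among the strongest peaks, chosen for naming after their values were seen, the first was at IV: 14033730 to 14034445 (signal 1118, rank 2 in replicate 1 and 1 in replicate 2) with its summit inside the gene of the microRNA mir-52. The second, at V: 12303436 to 12303823 (signal 1099), had its summit in an intron of frm-7 next to the snoRNA genes C51F7.3 and C51F7.4. The fourth, at IV: 11025973 to 11026404 (signal 842), lay 91 bp upstream of mir-51, a member of the same microRNA family as mir-52. Other noncoding RNA genes also lay within 200 bp of the summits at mir-52 (among them Y37A1B.335) and mir-51 (F36H1.17), so these peaks cannot be assigned to the microRNA genes alone. Peaks also covered mir-35 to mir-38, a cluster expressed in embryos (II: summit at 11537752, signal 259), and the spliced leader genes sls-2.4 (summit at I: 4172339, signal 708), sls-2.2 (388) and sls-2.1 (349.8). The strongest tRNA gene peak had its summit at X: 489918 (signal 755).

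Promoters of protein-coding genes held more summits than random placement gave. Of the 642 summits, 298 (46.4%) were in a promoter, against 27.4% ± 1.80 (SD over the 1000 placements). Coding exons held 3.58% against 17.96% ± 1.51 and intergenic sequence 12.5% against 21.9% ± 1.59, and noncoding genes 11.1% against 3.15% ± 0.661. Each of these 4 differences had a permutation p of 0.002, the smallest possible, and an adjusted p of 0.0035. Shares in introns (24.9% against 26.8%, adjusted p = 0.373 by permutation), 3' UTRs (1.40% against 2.42%, 0.148) and 5' UTRs (0.156% against 0.344%, 0.711) did not pass. With the 5' ends of noncoding genes included, 84.1% of summits were at a promoter, against 39.4% in random placements. Of the 399 summits away from small RNA genes, a set chosen after seeing the data, 57.6% were in a promoter of a protein-coding gene, against 27.5% in random placements. The excess at promoters therefore did not rest on the small RNA gene peaks.

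**Figure D3:**
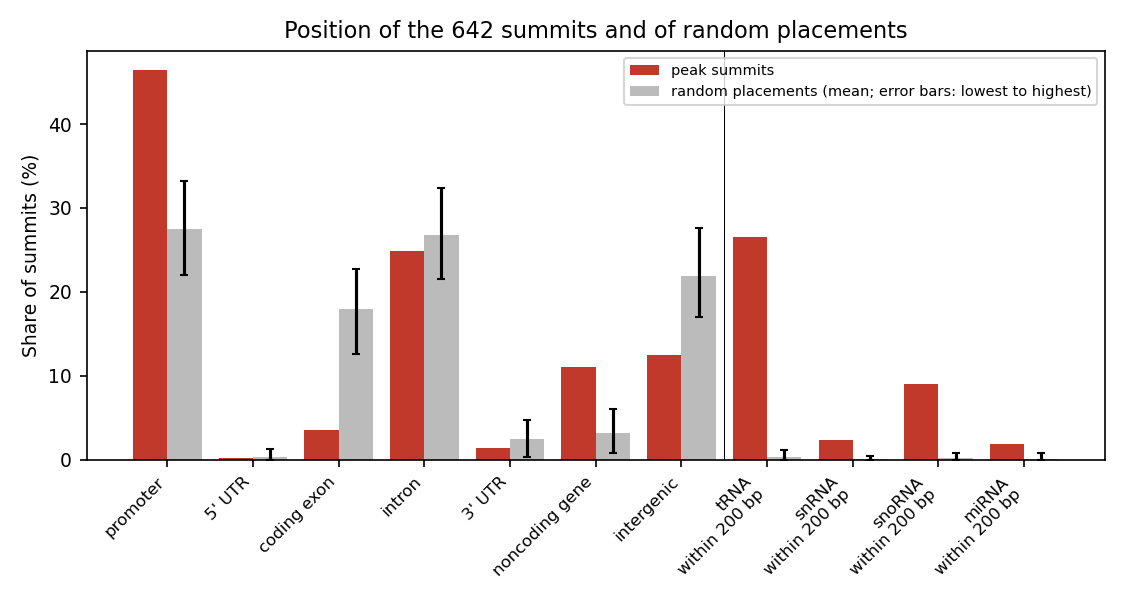
Share of the 642 summits (red) and of random placements (grey, mean, with bars from the lowest to the highest of 1000) in each class of sequence, in percent, and within 200 bp of 4 classes of noncoding RNA gene. Promoters (46.4% against 27.4%) and tRNA genes (26.5% against 0.292%) stand above the placements, and coding exons (3.58% against 17.96%) below.

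A total of 371 of 19973 protein-coding genes (1.86%) had a summit in a promoter. Ribosomal protein genes had them most often among the 18 preset lists: 13 of 81 (16.05%) against 1.80% of other genes, an odds ratio of 10.4 (Fisher's exact test, two-sided, adjusted p = 5.5e-08) from 13 distinct peaks. The strongest were at rpl-3 (III: 3867854 to 3869587, signal 442), rps-11 (IV: 11602641 to 11603280, 272), rps-26 (I: 14759930 to 14760626, 255) and rpl-15 (IV: 653480 to 654576, 224). A small RNA gene lay within 200 bp of the summit at rps-26. Of the 13 genes, 12 had a peak without a small RNA gene near it (odds ratio 12.1, Fisher's exact test, adjusted p = 4.4e-08, chosen after seeing the data), and 7 had a peak ranked in the top 642 of both replicates.

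Genes of histones, the proteins that package DNA, followed, with 11 of 72 (15.3%) and an odds ratio of 9.79 (Fisher's exact test, adjusted p = 7.7e-07). These 11 genes were reached by 6 distinct peaks, since neighbouring histone genes have overlapping promoter windows. The strongest were at his-31 and his-32 (IV, summit at 8334508, signal 349.7) and at his-67 and his-68 (I, summit at 9988979, signal 235.3). When each peak was assigned only to its nearest gene, the odds ratio was 7.57 (Fisher's exact test, adjusted p = 0.00069). In replicate 1 alone it was 14.9, and with only the peaks ranked high in both replicates 16.9. Ribosomal protein genes had odds ratios of 7.28 and 8.70 in these settings, so which list came first depended on the peaks used. Histone genes have near-identical copies, and reads that fit several of them make the assignment to a single gene uncertain.

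Stress response genes had peaks at 4 of 31 promoters, from 4 distinct peaks (odds ratio 7.90, Fisher's exact test, adjusted p = 0.0112). These were xbp-1, a transcription factor of the unfolded protein response (signal 216), hsp-1 (199), hsp-3, an endoplasmic reticulum chaperone (187), and hsp-60, a mitochondrial chaperone (176). Genes of the mitochondrial respiratory chain had them at 4 of 40, from 4 distinct peaks (odds ratio 5.92, adjusted p = 0.0226 by Fisher's exact test), all of them cytochrome c oxidase subunits: cox-6A (signal 247), cox-5A (219), cox-6B (177) and cox-5B (147). A small RNA gene lay within 200 bp of the summit at cox-6A. Cell cycle genes had them at 4 of 42, from 4 distinct peaks (odds ratio 5.61, Fisher's exact test, adjusted p = 0.0226): sas-5, which acts in centriole assembly (signal 219), lin-35, the retinoblastoma homologue (205), cki-1, an inhibitor of cyclin-dependent kinases (177), and spd-5, a centrosome scaffold protein (153).

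These last 3 calls depended on the peaks used. From replicate 1's top 642 regions alone, the adjusted p was 0.0511 for stress response, 0.369 for the respiratory chain (odds ratio 3.43) and 0.0924 for the cell cycle. With each peak assigned to its nearest gene, the adjusted p was 0.0569 for both the respiratory chain and the cell cycle, in the stronger 321 peaks it was 0.134 for both, and without peaks near small RNA genes it was 0.0632 for the respiratory chain.

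Chemoreceptor genes, which encode receptors of sensory neurons, had fewer promoter peaks than other genes: 6 of 1309 (0.458%) from 6 distinct peaks, an odds ratio of 0.231 (Fisher's exact test, adjusted p = 6.3e-05). Without peaks near small RNA genes, a set chosen after seeing the data, the odds ratio was 0.145. The strongest were at sre-23 (signal 763), where the snoRNA gene ZK265.10 lay within 200 bp of the summit, sre-1 (256), sri-5 (215) and srh-269 (200), where a small RNA gene also lay within 200 bp.

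The other 12 lists did not pass the test. Translation factors and aminoacyl-tRNA synthetases had peaks at 4 of 69 genes (Fisher's exact test, adjusted p = 0.0887), with the strongest at ears-2 (signal 412) and eif-3.C (283), and mRNA splicing at 3 of 40 (0.0887), with the strongest at snr-1 (336) and snr-4 (203). Nuclear hormone receptors had peaks at 3 of 269, among them nhr-255 (signal 341) and nhr-41 (289), each with a small RNA gene within 200 bp of the summit. Maternal and germline regulators had 1 of 32 (mex-1, signal 239), muscle structure 1 of 34 (act-2, 169.7) and cuticle collagens 1 of 169 (col-185, 246). No promoter peak was counted among the 33 proteasome subunits, 12 endoderm and mesendoderm regulators, 42 other embryonic lineage regulators, 63 homeobox ceh genes, 24 pan-neuronal genes or 18 intestine terminal genes. With 1.86% of all genes counted, lists of this size could hold 0 by chance, and none of these 6 lists passed (Fisher's exact test, adjusted p from 0.877 to 1).

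Many of the strongest promoter peaks lay beside a small RNA gene, as did 75 of the 100 strongest peaks of any position. The count below is therefore no sign of a link between promoters and small RNA genes. Of the 20 protein-coding genes with the strongest promoter peaks, 12 had a tRNA, tRNA pseudogene, snoRNA or snRNA gene within 200 bp of the summit. These 12 were sre-23 (signal 763), egl-17, a fibroblast growth factor (755), T02E1.2 (749), egg-5, which acts in the transition from oocyte to embryo (708), cfim-2 (505), gcy-33 (479.7), C28G1.2 (472), F55A11.6 (433), F28H6.7 (421), C41C4.9 (408), wrt-3 (402) and Y75B12B.11 (397). At egg-5 (I: 4168984 to 4171589) the neighbour was the spliced leader gene sls-2.4, whose 5' end lay 133 bp from the summit. The other 8 genes were K12H4.5 (III: 8044487 to 8044780, signal 912), ftt-2 (599), atx-2, the ataxin-2 homologue (475), T13C5.6 (473), W01D2.3 (460.5), rpl-3 (442), ears-2 (412) and idhg-1, an isocitrate dehydrogenase subunit (384). All 20 were within rank 73 in both replicates.

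Peaks were not spread evenly over the chromosomes. X held 146 of the 642 peaks (22.7%, exact 95% interval 19.6 to 26.2%), more than its 17.7% of the genome's length (exact binomial test, two-sided, adjusted p = 0.00218) or its 13.7% of the protein-coding genes (1.7e-09). Chromosome III held 120 (18.7%) against 13.7% of the length (exact binomial test, adjusted p = 0.00138). Chromosome V held 76 (11.8%) against 20.9% (1.5e-08), and IV held 89 (13.9%) against 17.4% (0.025), although IV did not differ from its share of genes (0.132). Chromosomes I and II held 106 and 105 peaks and did not pass (exact binomial test, adjusted p = 0.353 and 0.442). From replicate 1's top 642 regions alone, X held 20.7% and did not pass (exact binomial test, adjusted p = 0.0589). The excess on X went with tRNA genes, of which X carries 276 of 612. Of the 170 peaks near tRNA genes, 74 were on X. Without those 170 peaks, X held 72 of 472 (15.3%, exact interval 12.1 to 18.8%; exact binomial test, adjusted p = 0.184), and chromosome III 21.4% (adjusted p = 1.9e-05); this set was chosen after seeing the data.

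**Figure D4:**
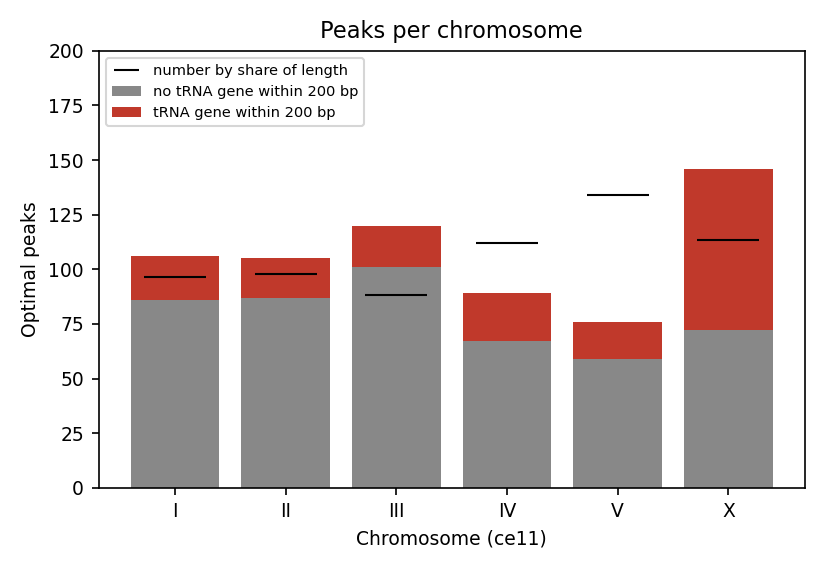
Number of the 642 peaks on each chromosome (bars, split by whether a tRNA gene lies within 200 bp of the summit) and the number given by the chromosome's share of the genome's length (black lines). X carried 74 of the 170 peaks near tRNA genes, and the other 72 were 15.3% of the 472 peaks away from tRNA genes, against 17.7% of the length, which did not pass (exact binomial test, adjusted p = 0.184); the lines are for all 642 peaks.

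The sequence at the summits was richer in G and C than the flanks (48.9% ± 8.53 against 36.1% ± 8.77, SD over 642 and 1284 windows). Of 2080 6-mers, 509 were more frequent at summits and 336 less frequent in this comparison, which does not match base composition. The 5 most significant of the more frequent 6-mers were AGAGCG, present in 14.5% of summit windows and 2.18% of flanks (odds ratio 7.60, Fisher's exact test, adjusted p = 2.9e-21), CGAACC (14.8% against 2.49%, adjusted p = 2.6e-20), GCGCGC (9.50% against 0.779%, 3.8e-18), AGCGCG (9.50% against 1.01%, 2.0e-16) and GAACCC (12.31% against 2.18%, 2.5e-16). When the set was divided after seeing the data, AGAGCG passed both at the 170 tRNA gene peaks (odds ratio 16.3, Fisher's exact test, adjusted p = 3.5e-15) and at the 399 peaks away from small RNA genes, miRNA genes not counted (4.98, 6.8e-07). AGCGCG also passed in both (odds ratio 8.53, Fisher's exact test, adjusted p = 0.00262, and 14.7, 4.7e-12). At the tRNA gene peaks, CGAACC was in 42.4% of windows and GAACCC in 33.5%. Summits there lay a median of 27.5 bp inside the gene, so the windows hold tRNA gene sequence. Identical copies exist for 472 of the 612 tRNA genes, so these windows are not independent. Tests at the tRNA gene peaks therefore cannot tell a bound sequence from sequence that tRNA genes share. At the peaks away from small RNA genes, the odds ratio of CGAACC was 1.05 and that of GAACCC was 1 (adjusted p = 1 for each), while GCGCGC was in 12.03% of windows against 0.752% of flanks (odds ratio 18.1, Fisher's exact test, adjusted p = 4.0e-15). CTCCGC (14.3% against 2.01%) and GAGGGA (13.8% against 2.26%) were also among the 10 most significant of the more frequent 6-mers there. GCGCGC did not pass at the tRNA gene peaks (odds ratio 2.01, Fisher's exact test, adjusted p = 1). These smaller sets, tRNA gene peaks and peaks away from small RNA genes, gave 276 and 277 more frequent 6-mers. Against windows of equal GC content from the same chromosome, a control added after seeing the data, 161 6-mers were more frequent at the 642 summits, 145 at the tRNA gene peaks and 68 at the peaks away from small RNA genes. The count thus depended on the control windows, which differed from the flanks in base composition and also in distance from the summit. The 5 6-mers passed against these windows with odds ratios of 4.10 for AGAGCG, 4.38 for CGAACC, 3.27 for GCGCGC, 3.10 for AGCGCG and 3.69 for GAACCC (Fisher's exact test, adjusted p from 9.3e-14 to 6.5e-06). At the tRNA gene peaks AGCGCG did not pass there (odds ratio 2.79, Fisher's exact test, adjusted p = 0.154), and at the peaks away from small RNA genes GCGCGC (6.28, 1.8e-08), GAGGGA (3.49, 1.1e-05), CTCCGC (2.49, 0.000773) and AGAGCG (2.43, 0.0128) did. The size of some of these differences depended on the data used, although all 5 6-mers passed under every alternative set before the data were examined. In replicate 1 alone the odds ratios of AGAGCG, GCGCGC and AGCGCG were 4.96, 7.04 and 5.55, in replicate 2 alone that of AGCGCG was 5.97, and over those alternatives GCGCGC ranged from 5.08 to 18.9, AGCGCG from 4.71 to 25.23 and GAACCC from 3.78 to 8.83.

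At the tagged gene itself, no peak lay in B0310.2 or within 5 kb of it, but weaker regions were more numerous there than an even spread over the genome gives: 13 in replicate 1, 7 in replicate 2 and 8 in the pooled list, against 4.49. Within 20 kb there were 19, 15 and 12 against 13.5, and within 50 kb 39, 29 and 24 against 31.4. These differences were not tested. The strongest pooled region within 5 kb ranked 987 (signal 121), below the 642 peaks, and the strongest ranked 1228 in replicate 1 and 992 in replicate 2. Within 20 kb the only peak was the tRNA gene peak at X: 489918 in the gene egl-17, which ranked 8 among all peaks, 10 in replicate 1 and 7 in replicate 2. Near unc-119 (III: 10902641 to 10908935), the gene that is mutated in the strain's background, no peak lay within 20 kb. The strongest pooled region within 20 kb of unc-119 ranked 1720 (signal 102), and the strongest ranked 3594 in replicate 1 and 2156 in replicate 2. Within 50 kb of unc-119 there was a peak of rank 243.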

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

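The tests of identical tRNA copies, of GC content at tRNA genes and of the tagged locus were fixed before their results were seen; the other tests in this part were chosen after the result was seen. The design has a single group, so no biological explanation was tested between groups; the density of tRNA genes on X was set against the peaks of that group alone.

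Data outside the 642 peaks also carried tRNA genes. Of the pooled regions ranked 643 to 1284, 47 (7.32%) had their summit within 200 bp of a tRNA gene, above the 0.467% that a count of 0 among 642 allows and above the highest of 1000 random placements (1.25%, permutation p = 0.002, the smallest possible). Counting these regions, 211 of 612 tRNA genes had a region. Among the remaining 28716 regions the share was 0.822%.

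The first pattern is the peaks near tRNA genes. How far reads shared between tRNA genes contribute was not settled by the test of identical copies. Of the 140 tRNA genes whose whole sequence occurs once in the nuclear genome, 19.3% had a peak, against at most 2.86% in random placements. The 472 genes with identical copies had one more often (31.4%, odds ratio 0.523 for unique genes, Fisher's exact test, two-sided, p = 0.00554), so shared reads may add to their number. A gene counted as unique can still share reads with near-identical genes. Its peak, within 200 bp, can also belong to a neighbouring tRNA gene, and the treatment of reads that align to several places is unknown. GC content does not account for the pattern, since placements matched on chromosome and GC content put at most 1.71% of summits near tRNA genes, against 26.5%. What also stays open is whether any anti-GFP precipitation from embryos would show these genes, which may be highly accessible, because no other tagged strain and no accessibility data were analysed here.

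The second pattern is the excess on X. It is consistent with the density of tRNA genes there, since the share on X was 15.3% without the peaks near tRNA genes, no longer above its 17.7% of the length. Peaks at the tagged locus made up little of the excess, since 1 peak lay within 50 kb of B0310.2 while X held 32.6 peaks more than its length gives. That stretch held only 24 pooled regions in all, background included. The test of extra copies of the locus thus had little room for another outcome, and no conclusion is drawn from it. The excess on chromosome III was not weighed.

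The third pattern is the peaks at ribosomal protein and histone promoters. Small RNA genes beside these promoters are argued against as the cause, because without such peaks the odds ratios were 12.1 and 12.5. For the 2 lists counted together, GC content is argued against as the whole cause. The GC-matched placements reached at most 15 genes of these lists, with a mean of 3.49, and the peaks reached 24. Neither list was counted alone in these placements, so they do not decide the question for the 11 histone genes or for the 13 ribosomal protein genes by themselves. A stricter bound set first, that the placements stay under 12 genes, was not met and was replaced after its result was seen. Accessibility of strongly expressed promoters could give the same pattern and was not tested.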

How the results depend on the processing

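Of 110 alternative values for the main results and the lists that passed, 86 kept their direction, their side of the threshold or, for counts, stayed within 1.5 times. Overlap of the replicates' top regions (51.7 to 74.1%), their rank correlation (0.602 to 0.691), the promoter share, the 4 noncoding classes, and the ribosomal protein, histone and chemoreceptor lists did so under every alternative run. Of the rest, the number of peaks was 398 when only peaks ranked in the top 642 of both replicates counted. The alternatives without peaks near tRNA or small RNA genes, with only tRNA gene peaks, with GC-matched control windows, and, for lists and noncoding classes, with peaks ranked high in both replicates were chosen after seeing the data. X held 15.3% without tRNA gene peaks, 17.8% without small RNA gene peaks and 20.7 to 23.7% with a replicate left out, where the lowest, without replicate 2, did not pass (exact binomial test, adjusted p = 0.0589). Fewer lists passed with the nearest gene only (3), the stronger 321 peaks (3) and the peaks ranked high in both (3), and 2 to 5 passed with either replicate left out. Odds ratios that no longer passed, in that order of settings, were 5.63, 5.59 and 4.74 for the respiratory chain (5.45 without small RNA gene peaks) and 5.34, 5.31 and 4.50 for the cell cycle. With a replicate left out the ranges were 3.43 to 5.75, 5.03 to 7.01 and, for stress response, 7.02 to 7.67. Without replicate 2, that is in replicate 1 alone, these 3 lists did not pass. Enriched 6-mers numbered 277 and 276 away from small RNA genes and at tRNA genes and 161 with GC-matched control windows, and the odds ratio of GAACCC was 1 in the former. The best rank was 987 within 5 kb of B0310.2, and 5022 within 5 kb and 243 within 50 kb of unc-119. The causes of these changes were not tested. Of 50 genes named from promoter peaks, 50 ranked in the top 642 of replicate 2 and 44 in that of replicate 1. Leaving out a replicate gives no value for the number of peaks, the overlap, the correlation or the pooled ranks near the transgene's genes. The top 642 of the pooled list were the main peaks themselves, so that alternative is void, and ranks near the tagged gene in ce10 were not run. No paired analysis was possible because there is a single group. Depth is unknown and sets no stated limit.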

Other observations

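The tests in this part were chosen after the results were seen. Genes for tRNAs of nearly every kind had peaks. All 20 standard amino acids were represented, from 16.7% of the tRNA-Trp genes to 46.2% of the tRNA-Cys genes, and no isotype passed the test against the others (Fisher's exact test, two-sided, adjusted p from 0.874 to 1 over 22 classes). The classes were small, with 12 tRNA-Trp and 13 tRNA-Cys genes, so differences between isotypes could have been missed. The selenocysteine tRNA gene had no peak. Annotated tRNA pseudogenes rarely had a peak, with 3 of 209 (1.44%) against 175 of 612 tRNA genes (28.6%; Fisher's exact test, two-sided, odds ratio 27.5, adjusted p = 2.9e-21 over 3 comparisons). On X, 76 of 276 tRNA genes (27.5%) had a peak and on the autosomes 99 of 336 (29.5%), a difference that did not pass (Fisher's exact test, adjusted p = 0.653). Among tRNA genes, 587 matched the B box, the internal promoter element of RNA polymerase III genes, and their share with a peak (28.3%) was set against that of the 25 without a match (9 of them with a peak) and the difference did not pass (Fisher's exact test, adjusted p = 0.653).

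A hypothesis is that part of the snoRNA peaks mark genes transcribed from a tRNA-like promoter. The B box consensus was within 100 bp of the summit at 26 of 58 snoRNA gene peaks (44.8%) and in 0 of 116 flanking windows (Fisher's exact test, two-sided, p = 3.6e-15), and none of these 58 summits was within 200 bp of a tRNA gene. The summits lay upstream of the snoRNA gene, at a median of -44 bp, where such an element may stand. At tRNA gene peaks the consensus was in 88.2% of windows and 8.82% of flanks. Summits there lay a median of 27.5 bp inside the gene, and 587 of the 612 tRNA genes match the B box. That share therefore follows largely from the position of the summits and does not bear on the hypothesis. The other snoRNA gene peaks had no match to the consensus.

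A second hypothesis, that peaks away from tRNA, tRNA pseudogene, snoRNA and snRNA genes could mark unannotated genes of this kind, was not supported by the B box. The consensus was in 15 of 399 windows (3.76%) and 28 of 798 flanks (3.51%; 12 of the 399 peaks lay near a miRNA gene; Fisher's exact test, two-sided, p = 0.87). What binds at these peaks was not tested.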
